A study of Mus musculus with 2 samples.

How the data were processed

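H3K27ac ChIP-seq peak lists of embryonic intestine were analysed, 1 list for each of the 2 pools of embryos, 1 called on both pools together and 1 of replicated peaks. Per the text files deposited with the lists, the peaks of each pool were derived from the alignment of that pool and its own control alignment, those of both pools together from both alignments and both controls, and the replicated peaks from the other 3 lists. The genome build is mm10, per the labels of the lists. The aligner, the peak caller, its thresholds and the rule that makes a peak replicated are not given in the sources used here. Every replicated peak is also a peak of the list called on both pools together.

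The lists are in narrowPeak format, per the deposited text files. The signal value of each peak was deposited by the authors, made against the control alignment, and its scale is not stated. It was used to describe, rank and filter peaks within a list. For gene lists compared between the pools, log2 ratios were centred on their median over shared peaks, which was −0.055 for replicate 1 against replicate 2. Values given as mean ± SD over the pools were not centred, so an SD can include an offset between the lists. The −log10 p-value and −log10 q-value of each peak were likewise deposited by the authors. Read counts and control tracks were not analysed here, so the depth of each pool is unknown and no value is corrected for it; the numbers of peaks of the pools can differ with depth alone. The largest p-value among the peaks of replicate 1 was 0.00956 and the largest q-value 0.504, so the deposited per-pool lists include weak peaks; 76.1% of the peaks of replicate 1 and 68.7% of those of replicate 2, and 98.8% of the replicated peaks, had −log10 q of at least 2. Both pools came from separate embryos, so their difference holds biological and technical spread together, and with 2 pools no test between pools was made for single peaks. Intervals given for shares of peaks or genes are 95% Wilson intervals and cover counting error only.

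The replicated list was the main list. Peaks on unplaced scaffolds were left out of all location results. Protein-coding genes on chromosomes 1 to 19, X and Y came from GENCODE release M21, with the 5' end of the gene as its TSS, and sequence from the GRCm38 assembly, of which mm10 is the browser name. A promoter peak overlaps the 1 kb on either side of a TSS; every other peak is distal and was assigned to the nearest TSS within 100 kb of its midpoint. A promoter's signal is that of its strongest promoter peak, and the mean ± SD is over the strongest promoter peak in the list of each pool. Peaks of the pools counted as shared where they overlapped by at least 50% of either peak. Overlaps were compared with 100 circular shifts of the peaks of each chromosome, and signals were paired by largest mutual overlap.

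The 23 gene lists covered cell types of the gut wall, other cell types that dissected gut could hold, other organs, housekeeping, proliferation, Hox and olfactory receptor genes. All listed genes but the erythroid gene Ahsp were found in the annotation. Promoter peaks and large domains in a list were compared with all other protein-coding genes by two-sided Fisher's exact tests, and distal peaks per gene with 10000 random lists matched on 10 classes of the sequence nearer to that TSS than to any other. Signals between the pools were compared over lists with shared peaks near at least 5 genes against 10000 random lists matched on the number of shared peaks, two-sided; for the gut mesenchyme list these draws were repeated 10 times after the result had been seen. Adjusted p-values are Benjamini-Hochberg values over the lists of a test, or over the 22 consensus sequences. Where a sequence was compared between gene lists, they are over the pairs of sequence and list compared. Lists share the same pools, and genes in a list can share peaks, so these p-values measure how far a list stands from other genes in these samples.

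Distal peaks less than 10 kb apart were joined, ranked by the sum of width times signal, and called large above the point where the slope of the scaled ranked curve passes 1. Consensus sequences were searched on both strands of each distal peak and of a window of the same width 10 kb away that overlapped no peak of any list. Peaks and windows were compared by an exact binomial test on the pairs with the sequence in only 1 of them, and each ratio was set beside up to 100 orders of the same consensus columns with the same number of CG steps. A sequence was called over-represented at an adjusted p below 0.05, a ratio above 1 and a ratio above more than 95% of its shuffled forms. The adjusted p of the E-box and of the olfactory receptor promoters were too small to be computed and are not printed.

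Genes named in the text were fixed by rule: all Hox genes by cluster, a set of 31 key genes of gut and other tissues, the 3 members of each list with the highest promoter signal and up to 3 members without a promoter peak in alphabetical order, the genes nearest the 20 highest domains and the 10 strongest peaks. This rule, the groups, gene lists, consensus sequences, tests and alternative settings were chosen before the data were examined. Genes outside the rule are members of a list counted in the same sentence or are said to have been picked afterwards.

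The alternative settings fixed then were a TSS window of 2.5 kb, every protein-coding transcript start, the list called on both pools together, −log10 q of at least 2, an overlap of 1 base, each pool's own list in place of the replicated list, assignment within 50 kb, random lists without matching, joining within 5 kb, ranking by covered bases, control windows 5 kb away, the central 200 bases of peaks, and distal shared peaks alone. Alternatives added after the data had been seen were −log10 q of at least 10, the exclusion of noncoding start sites before joining, the exclusion of peaks within 5 kb of a TSS, and random lists matched on 10 classes of the CpG ratio of the 1 kb around the TSS.

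The procedures were tested on simulated data. With 60.4% of 39677 peaks planted as shared, 60.5% were found and 0.966% after shifting. Of simulated lists of 25 genes with peaks at 90% or 15% of members, 97.5% and 95% were called over 21938 genes, and 1.73% of unchanged lists. A planted 3-fold rise of distal peaks was detected at p below 0.05 in 85.3% of lists and no rise in 5.67%. All planted consensus sites were found in 5000 windows, and of 10000 simulated domains with 500 large ones 566 were called large. The simulated large domains were set apart from the others by a gap, so a ranked curve without one was not tested. Simulated windows and controls had the same base composition, so a difference in GC content was not tested either. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, numba 0.67.0, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9 were used.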

Results

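H3K27ac, an acetyl mark of histone H3 found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the intestine of C57BL/6NCrl mouse embryos of both sexes at embryonic day 15.5. The 2 biological replicates were separate pools of 78 embryos (replicate 1) and 62 embryos (replicate 2). They form a single group with no second tissue or stage, so the comparisons made here are between the replicates, between gene groups and between regions of the genome. Peak lists give no read totals, and the sequencing depth of each pool is therefore unknown. All coordinates are mm10.

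The replicated list held 51691 peaks with a median width of 594 bp, which covered 42.6 Mb or 1.56% of chromosomes 1 to 19, X and Y. The highest signal, 47.4, was at the zinc finger gene Zfp143 (chromosome 7, 110061592 to 110063294, inside the gene with its midpoint 1226 bp from the start site), with 42.2 ± 4.22 (SD, n = 2) in the pools. Arid1a, a subunit of a chromatin remodelling complex, followed with 46.7 and the transcription factor gene Sp3 with 46.3. Kmt5b, Arrdc3, Hist4h4, Dyrk1a and Cap1 were also among the 10 strongest. The other members of that group lay outside promoters, 5933 bp from the start site of Zfp869 and inside Kansl1, 26763 bp from its start site. Not every replicated peak was found by overlap in the list of each pool. Of those on chromosomes 1 to 19, X and Y, 82.7% were in the lists of both pools, with a median signal of 4.33. A further 8.05% were in that of replicate 1 only and 8.52% in that of replicate 2 only, with medians of 3.06 and 3.05. The remaining 0.77% were in neither list, with a median of 2.68.

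Replicate 1 gave 78524 peaks and replicate 2 gave 96031. Of the peaks of replicate 1, 58.9% shared at least 50% of either peak with a peak of replicate 2 (95% Wilson interval 58.6 to 59.3%), and 48.5% of the peaks of replicate 2 were shared in turn (48.2 to 48.8%). Lists shifted at random along the chromosomes shared 2.43% and 2.03%, and none of 100 shifts came near the observed overlap (permutation p = 0.0099, one-sided, the smallest that 100 shifts can give). Peaks with −log10 q of at least 2 were found in the full list of the other pool in 68.8% of cases for replicate 1 and 62.2% for replicate 2. With −log10 q of at least 10, a threshold chosen after the lists had been seen, the values were 99.3% and 99.6%. With the lists of both pools held to the threshold, 63.0% of replicate 1 and 57.3% of replicate 2 peaks were shared at 2. At 10 these shares were 79.0% and 83.5%. Shared peaks of replicate 1 lay within 1 kb of a protein-coding transcription start site (TSS) in 30.4% of cases and those without a partner in 7.87%; the values for replicate 2 were 30.2% and 7.16%. Median signals were 4.15 for shared and 2.98 for unshared peaks in replicate 1, and 4.28 and 2.91 in replicate 2.

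Across 42368 one-to-one pairs of shared peaks, log2 signals of the pools correlated with Pearson's r = 0.813 (95% interval 0.809 to 0.818 from resampled chromosomes) and Spearman's rho = 0.701. This correlation is across peaks of 1 pair of pools, and peaks are not independent replicates. The log2 difference between pools had an SD of 0.45, and 97.2% of pairs lay within 1 log2 unit of the median difference.

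Promoters carried a large share of the acetylation. Of the replicated peaks on these chromosomes, 13767 of 51685 (26.6%, 95% Wilson interval 26.3 to 27%) lay within 1 kb of a protein-coding TSS, against a mean of 2.35% for shifted peaks (permutation p = 0.0099, one-sided, the smallest that 100 shifts can give). Introns held 40.1%, intergenic sequence 28.1% and exons 5.2% of the peaks. Promoter peaks had a median signal of 6.56, a median GC content of 58.1% and a median CpG ratio (observed over expected) of 0.664. Distal peaks, 37918 in number, had medians of 3.61, 50.3% and 0.223. The promoter share was 16.4% in the peaks called on both pools together and 44.7% with −log10 q of at least 10. In total 11367 of 21938 protein-coding genes (51.8%, 51.2 to 52.5%) had a replicated peak within 1 kb of the TSS.

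Genes of the gut epithelium and of the gut mesenchyme were acetylated at their promoters more often than other genes. All 29 genes of the intestinal epithelium list carried a promoter peak, against 51.8% of other genes (adjusted p = 6.6e-08, Fisher's exact test). Among them were Elf3, an ETS-family factor of epithelia, with a signal of 14.7 and 11.3 ± 0.644 (SD, n = 2) in the pools; Grhl2, a regulator of epithelial junctions, with 13.7 (12.8 ± 0.210); and Cdx2, the homeobox factor of intestinal identity, with 13.2 (11.9 ± 0.339; peak at chromosome 5, 147303748 to 147308714, across the TSS). Sox9, Hnf4a, Gata4 and Shh had signals of 7.62, 7.0, 6.66 and 5.53.

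Of the gut mesenchyme list, 29 of 32 genes had a promoter peak (adjusted exact p = 2.1e-05). The homeobox genes Meis1 and Pbx1 had signals of 22.9 and 19.4, and Foxf1, a forkhead factor of visceral mesenchyme, had 18.2 (17 ± 1.84, SD, n = 2; peak at chromosome 8, 121078616 to 121084228). Nkx2-3 had 6.70. Barx1, a stomach mesenchyme factor, Osr1 and Prrx1 were the members without one; Osr1 had one at another coding transcript start (4.67). In the smooth muscle list 17 of 20 genes had a peak (adjusted exact p = 0.0055), with Srf at 14.1, the tropomyosin genes Tpm1 and Tpm2 at 12.5 and 9.37, the actin gene Acta2 at 6.97 and Myocd, the gene of an SRF coactivator, at 5.49. Csrp1, Mylk and Smtn had their replicated peaks at other coding transcript starts (7.65, 9.37 and 14.9), and with every such start counted the list stood at 20 of 20.

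Genes of general cell functions were high as well. Housekeeping genes had a promoter peak in 20 of 20 cases (adjusted exact p = 1.8e-05), led by Actb at 31.7 (28.3 ± 1.22, SD, n = 2), Polr2a at 20.6 and Cltc at 20.2. Proliferation genes had one in 20 of 22 cases (adjusted exact p = 0.00042), led by Birc5 at 20.7, Aurkb at 15.2 and Mcm6 at 14.6, while Bub1 and Mcm3 had none. When lists were instead set against random lists of the same promoter CpG ratio, a comparison added after the data had been seen, the proliferation list no longer passed (90.9% against 81.2%, adjusted permutation p = 0.51). The epithelium (100% against 49.9%), mesenchyme (90.6% against 59.7%), smooth muscle (85% against 50.8%) and housekeeping lists (100% against 74.6%) still passed.

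**Figure D1:**
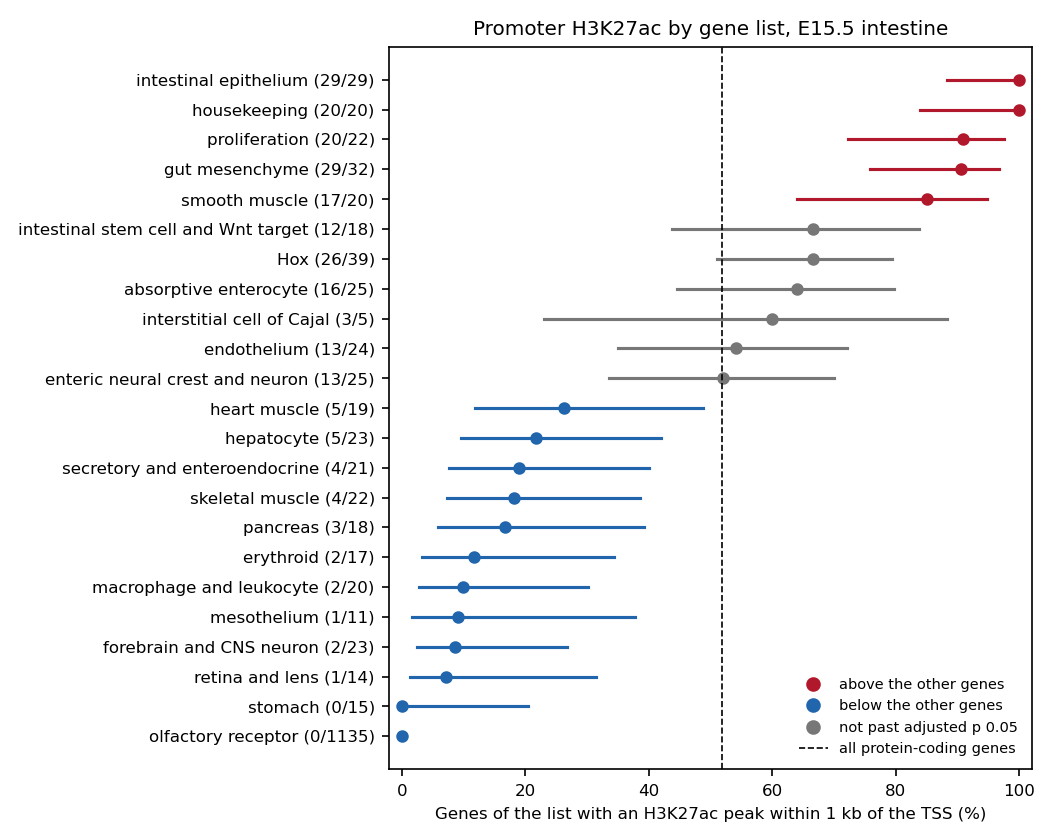
Percent of the genes of each list with a replicated H3K27ac peak within 1 kb of the TSS (points) with 95% Wilson intervals (bars), and the percent of all protein-coding genes, 51.8%, as a dashed line. The intestinal epithelium and housekeeping lists stand at 100%, the stomach and olfactory receptor lists at 0%.

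Markers of mature and of rarer gut cells were mixed. Of the absorptive enterocyte genes 16 of 25 had a promoter peak (adjusted exact p = 0.28). Mttp, needed for lipoprotein assembly, had 24.5, Dpp4 8.95, Cdhr5 8.17 and the fatty acid binding protein gene Fabp1 2.60, whereas the lactase gene Lct, Ace2 and Anpep had none; Anpep had one at another coding transcript start (6.43). Against random lists of the same promoter CpG ratio, where 27.4% of genes had a peak, this list did pass (64%, adjusted permutation p = 0.00092). Stem cell and Wnt target genes had a peak in 12 of 18 cases (adjusted exact p = 0.28); the Wnt target Axin2 had 32.4, Myc 20.1 and Lrig1 10.3, and the stem cell markers Lgr5 and Ascl2, like Lef1, had none, apart from a peak at another coding start of Ascl2 (5.49). Secretory and enteroendocrine genes were acetylated less often than other genes, in 4 of 21 cases (adjusted exact p = 0.0057), but this call ended in each pool alone (33.3% in replicate 1, 47.6% in replicate 2), with both pools together (42.9%) and against lists of the same CpG ratio (adjusted permutation p = 0.081). Pou2f3, Dclk1 and Agr2 were at 4.18, 3.77 and 3.48, and Neurog3, Arx and Chga had no replicated promoter peak. Nor had Atoh1, the factor that starts secretory fate, although each pool's own list held one (2.97 ± 0.185, SD, n = 2). The peaks of the pools were taken from each list by itself, so these values need not describe the same site.

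Enteric neural crest and neuron genes had a promoter peak in 13 of 25 cases (adjusted exact p = 1), among them Erbb3 at 9.65, Hand2 at 9.64, Ednrb at 7.90, Phox2b at 3.45 and the receptor gene Ret at 3.35. Foxd3, Chrna3 and Dbh had none. Sox10 had one in each pool's own list (3.09 ± 1.11, SD, n = 2), not necessarily at the same site, but none in the replicated list. Of the genes of the interstitial cells of Cajal, the pacemaker cells of the gut wall, 3 of 5 had one (adjusted exact p = 1), Etv1 at 15, Ano1 at 5.38 and Kit at 4.39. Endothelial genes had one in 13 of 24 cases (adjusted exact p = 0.92), with Ecscr at 7.63, Eng at 7.20 and Cldn5 at 3.75, and with none at Cdh5, Emcn and Erg; Pecam1 had one at another coding transcript start (3.50). With peaks of −log10 q of at least 10 alone, 8.33% of the endothelial genes had a promoter peak and the list was below the other genes (adjusted exact p = 0.00065). With the peaks called on both pools together it was above them, at 87.5% (adjusted exact p = 0.0061), as was the enteric neural list, at 80% (0.038).

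Genes of other organs, of macrophages and blood cells, and of mesothelium were acetylated less often than other genes. Some of these cell types can be part of dissected gut, and a low share does not show that a cell type was absent. The counts were 2 of 20 for macrophage and leukocyte genes (adjusted exact p = 0.00042; Cd68 at 5.09 and Cx3cr1 at 3.21), 2 of 17 for erythroid genes (0.0022; Klf1 at 7.66 and Nfe2 at 3.87) and 1 of 11 for mesothelium genes (0.0075; Upk3b at 5.84). They were 3 of 18 for pancreas genes (adjusted exact p = 0.0057; Nr5a2, Mnx1 and Pnliprp1), 5 of 23 for hepatocyte genes (0.0078; Cebpa at 11.5, Apoh at 9.64 and Ttr at 4.29 the highest), 4 of 22 for skeletal muscle genes (0.0042; Mylpf at 9.04 the highest) and 5 of 19 for heart muscle genes (0.049; Myl4 at 8.99 the highest). Forebrain genes had a peak in 2 of 23 cases (adjusted exact p = 8.5e-05; Dlx2 and Dlx1), retina and lens genes in 1 of 14 (0.0017; Opn1sw), stomach genes in 0 of 15 (8.0e-05) and olfactory receptor genes in 0 of 1135. Spi1, Gata1, Wt1, Ptf1a, Alb, Sox2, Foxg1, Myod1, Nkx2-5 and Rho had no replicated promoter peak.

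With every coding transcript start counted, all of these lists stayed below the other genes, but macrophage genes rose to 5 of 20 (adjusted exact p = 0.016; Runx1 at 4.86, Lcp1 at 3.09 and Coro1a at 2.68 added), pancreas genes to 4 of 18 (Cela1 at 6.0) and forebrain genes to 3 of 23 (Satb2 at 8.43). Of the 12 lower lists, secretory genes among them, 4 passed against random lists of the same promoter CpG ratio: forebrain (8.70% against 64.4%), mesothelium (9.09% against 51.2%), stomach (0% against 27%) and olfactory receptor genes (0% against 7.55%). In the peaks of replicate 2 alone the calls for heart muscle (42.1%), macrophage (35%), mesothelium (36.4%), pancreas (50%) and secretory genes ended, and 7 lists were below the other genes; in those of replicate 1 alone only the call for secretory genes ended. The call for heart muscle genes also ended with a TSS window of 2.5 kb (7 of 19, adjusted exact p = 0.20), and with the peaks called on both pools together the heart muscle, macrophage, mesothelium, pancreas and secretory lists all lost theirs (adjusted exact p of 0.15 or more).

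Along the Hox clusters, which encode position on the body axis, the highest signals were at genes of the Hoxb and Hoxa clusters. Promoter peaks were present at 26 of 39 Hox genes (adjusted exact p = 0.098; 30 of 39 and above other genes in replicate 1 alone, 0.0069, and with both pools together, 0.023), 10 of 11 in the Hoxa cluster on chromosome 6, 7 of 10 in Hoxb on chromosome 11, 3 of 9 in Hoxc on chromosome 15 and 6 of 9 in Hoxd on chromosome 2. Hoxb4 had the highest signal, 19.3 (17.3 ± 0.692, SD, n = 2), followed by Hoxb2 at 13.7, Hoxa4 at 13.1 and Hoxa1 at 11.4. Toward the other end of the clusters Hoxa10, Hoxa11, Hoxd10 and Hoxd11 were at 3.36, 4.55, 2.99 and 2.94. Hoxa13, Hoxb13, Hoxc10, Hoxc11, Hoxc12, Hoxc13, Hoxd12 and Hoxd13 had no replicated promoter peak. Nor had Hoxb1, Hoxb8, Hoxc5, Hoxc9 and Hoxd1 among the lower-numbered genes, although Hoxb8 (10.7) and Hoxc5 (14.6) had one within 1 kb of another coding transcript start. Hoxd3 and Hoxd4 have annotated start sites next to each other and share a peak of 5.96.

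**Figure D2:**
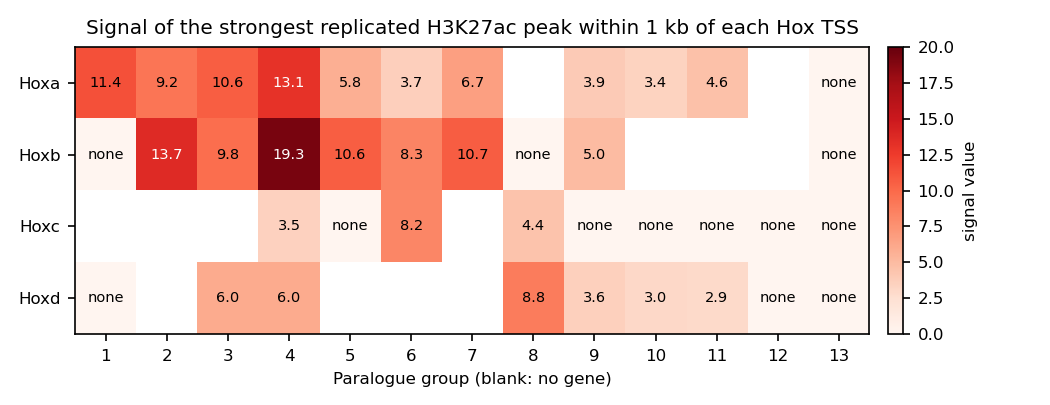
Signal of the strongest replicated H3K27ac peak within 1 kb of the TSS of each Hox gene, by cluster (rows) and paralogue group (columns), with "none" where there was no such peak. Hoxb4 stands highest at 19.3, and no group 13 gene has a peak.

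Distal peaks, those further than 1 kb from the 5' end of every protein-coding gene, were most numerous around epithelial genes. They include peaks at other coding transcript starts: with every such start counted, 35184 peaks stayed distal. The tests of distal peaks per gene were not run on those alone. Each distal peak was assigned to the nearest TSS within 100 kb, which placed 31283 of 37918 (82.5%). Intestinal epithelium genes had 8.52 distal peaks per gene, against 1.73 in random lists matched on the sequence available around each gene (adjusted p = 0.0015, permutation). Gata4 had 22, Hnf4a 14, Shh 13, Elf3 10, Grhl2 9, Cdx2 8 and Sox9 4 of them. Stem cell and Wnt target genes had 6.78 per gene against 2.31 (adjusted permutation p = 0.0059), with 32 at Lrig1, 6 at Axin2, 5 at Myc and 0 at Lgr5. Gut mesenchyme genes had 5.69 against 2.44 (adjusted permutation p = 0.0059), with 21 at Foxf1, 12 at Meis1 and 8 at Nkx2-3. Smooth muscle genes had 5.30 against 1.69 (adjusted permutation p = 0.0015), with 20 at Tpm1, 3 at Tpm2 and 2 at Acta2. Housekeeping genes had 3.20 against 0.940 (adjusted permutation p = 0.0059) and Hox genes 1.77 against 0.556 (adjusted permutation p = 0.0034). Random lists were not matched on promoter peaks. Autosomal genes with a promoter peak had 2.16 distal peaks each, against 1.43 over all genes. The part of promoter peaks in the excess or deficit of a list is therefore unknown. Numbers per gene were higher in the longer list of each pool alone, 14.6 for epithelium and 12.4 for gut mesenchyme genes in replicate 2 and 12.8 and 9.38 in replicate 1, while the ratios to random lists were 4.13 and 2.49 in replicate 2 and 4.53 and 2.37 in replicate 1.

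Fewer distal peaks than in random lists lay around forebrain genes (0.391 against 2.17, adjusted permutation p = 0.0075), erythroid genes (0.0588 against 0.870, adjusted permutation p = 0.039) and olfactory receptor genes (0.0273 against 0.726, adjusted permutation p = 0.0015). Endothelial genes had 3.42 against 1.71 (adjusted permutation p = 0.089) and absorptive enterocyte genes 3.36 against 1.80 (adjusted permutation p = 0.11). The other 12 lists had adjusted permutation p of 0.21 or more. Single genes without a promoter peak could have many distal peaks, such as Chga with 17 and Cdh5 with 10. When peaks within 5 kb of a TSS were also left out, an alternative added after the data had been seen, the Hox (2.5 times random lists, adjusted permutation p = 0.12), gut mesenchyme (1.93 times, 0.057) and erythroid lists (0.0946 times, 0.17) no longer passed; their ratios with those peaks were 3.18, 2.33 and 0.0676. Without matching on available sequence the Hox, housekeeping and forebrain lists did not pass and the absorptive enterocyte and endothelial lists did (adjusted permutation p = 0.047 for each); the endothelial list also passed with assignment within 50 kb (3.12 per gene, 0.024). The erythroid list did not pass in the peaks of replicate 1 alone (0.235 per gene) or with −log10 q of at least 10.

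**Figure D3:**
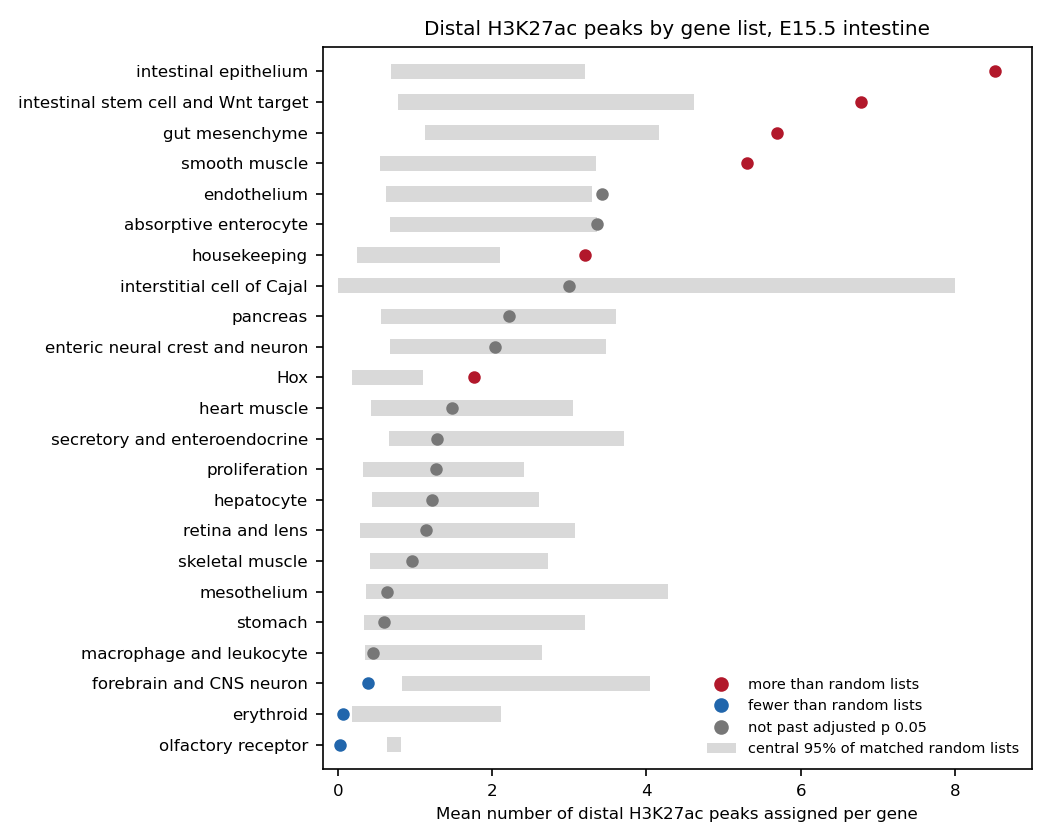
Mean number of distal replicated H3K27ac peaks assigned per gene of each list (points), with the central 95% of 10000 random lists matched on available sequence (grey bars). The intestinal epithelium list stands at 8.52, above its random range of 0.690 to 3.21.

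Distal peaks less than 10 kb apart were joined into 16097 domains, of which 787 passed the bend of the ranked curve of signal times width. These large domains held 27.7% of the distal sequence covered by peaks and 37.6% of its signal. The first ranked domain spanned 90309 bp near Cstad (chromosome 2, 30636144 to 30726452, 25 peaks), and the second 39161 bp near Zmynd8 (chromosome 2, 165850913 to 165890073). The third, near Il17b (chromosome 18, 61626057 to 61694007), contained the start sites of the noncoding genes Carmn, Mir143 and Mir145a, known from smooth muscle. The domain near Mrpl23 contained that of the imprinted gene H19 and the domain near Scyl1 that of the nuclear RNA Malat1; these noncoding genes were picked out after the domains had been seen. Ptch1, the hedgehog receptor gene, was nearest to the domain ranked 12. The remaining domains of the first 20 lay nearest to Zfp36l1, Rara, Lsp1, Sept9, Casc3, Bahcc1, Setd1b, Ski, Gins2, Actn4, Ddc, Irf2bpl and Midn, and 1 had no protein-coding TSS within 100 kb. With joining within 5 kb, 11 of the genes were again among those nearest the first 20, and with start sites of noncoding genes also excluded before joining, an alternative added after the data had been seen, 12 were.

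Large domains lay nearest to 671 genes, 3.06% of all. The share was higher for intestinal epithelium genes (10 of 29, adjusted p = 9.1e-08, Fisher's exact test; Krt19, Krt8, Krt18, Cdx1, Cdx2, Gata4, Hnf4a, Cldn3, Epcam and Elf3) and gut mesenchyme genes (8 of 32, adjusted exact p = 3.1e-05; Ptch1, Meis1, Col1a1, Col1a2, Zeb2, Gli2, Nkx2-3 and Foxf1). It was also higher for stem cell and Wnt target genes (4 of 18, adjusted exact p = 0.011; Nkd1, Rnf43, Ephb2 and Ephb3) and housekeeping genes (4 of 20, adjusted exact p = 0.013; Ywhaz, Actb, Ubc and Eef1a1). For smooth muscle genes it was 3 of 20 (adjusted exact p = 0.084; Csrp1, Tpm1 and Synpo2). The stem cell and Wnt target list lost its call with joining within 5 kb (16.7% of its genes) and with peaks of −log10 q of at least 10 (5.56%), and the housekeeping list when domains were ranked by covered bases alone (15%); with that ranking the smooth muscle list gained one (4 of 20, adjusted exact p = 0.023). With noncoding start sites excluded the same 4 lists were higher, with 14 of 29 epithelium and 6 of 32 gut mesenchyme genes (adjusted exact p = 0.0045), and smooth muscle genes stood at 2 of 20. Large domains are made of the distal peaks counted above, so these shares are not separate evidence. The tests were not matched on available sequence or on promoter peaks, so the part of either in the shares is unknown.

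Recognition sequences of several transcription factor families were more frequent in distal peaks than in paired windows of the same width 10 kb away. The distal peaks searched included those at other coding transcript starts and at noncoding start sites. No setting left these out, so their part in the ratios is unknown. Of 22 consensus sequences searched in 34619 pairs, 6 were over-represented relative both to the paired windows and to more than 95% of their own shuffled forms. The ETS consensus CCGGAAGT occurred in 1.4% of peaks and 0.540% of windows (ratio 2.58, adjusted exact p = 2.1e-30). The CAGCTG form of the E-box, bound by basic helix-loop-helix factors, was found in 39.5% and 26.6% (ratio 1.49), and the PU.1-type ETS consensus GAGGAAGT in 6.01% and 4.16% (ratio 1.44, adjusted exact p = 2.2e-28). The HNF4 consensus had a ratio of 1.38 (2.62% and 1.91%, adjusted exact p = 2.9e-10), the CArG box of SRF 1.13 (3.69% and 3.27%, adjusted exact p = 0.0028) and the TEAD consensus 1.12 (24.2% and 21.5%, adjusted exact p = 1.9e-17). In the narrower peaks of each pool alone the shares were lower, 23.4% to 25.3% for the E-box and 1.21% to 1.38% for HNF4, with ratios of 1.53 and 1.28 in both pools. AP-1 had a ratio of 1.14, with 95% of shuffled forms below it, and missed the second criterion.

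Several AT-rich consensus sequences were less frequent in the peaks, whose GC content was 50.7% against 45.7% in the windows. Those of CDX, GATA and FOX factors had ratios of 0.79, 0.88 and 0.92; the GATA and FOX ratios were above all of their shuffled forms and the CDX ratio above 89% of them. The CTCF consensus had a ratio of 0.88 (0.537% and 0.612%). The SRF call was lost in each pool alone (ratios 1.03 to 1.06), in the central 200 bases (1.03) and with −log10 q of at least 10 (1.11), and that of AP-1 was gained in all of these; HNF1, found in 29 peaks and 23 windows, passed only with windows 5 kb away (ratio 2.57).

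**Figure D4:**
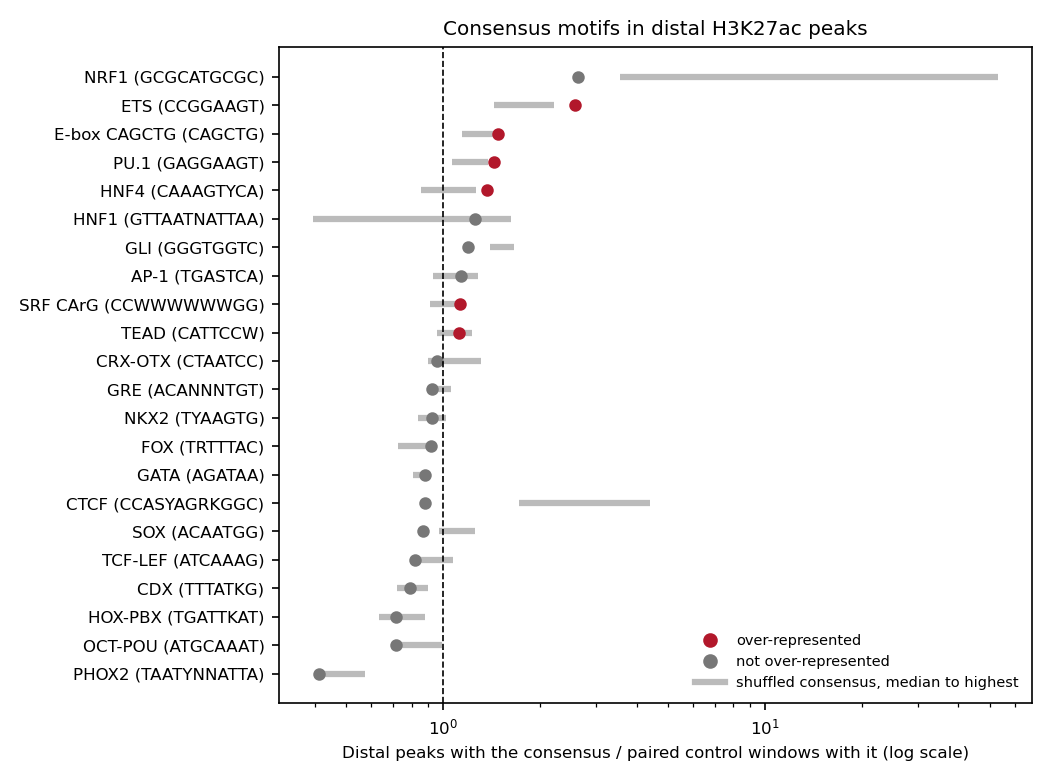
Ratio of distal replicated peaks to paired control windows containing each of 22 consensus sequences (points, log axis), with the span from the median to the highest ratio of its shuffled forms (grey bars). The 6 over-represented sequences are red, from TEAD at 1.12 to ETS at 2.58.

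Between the pools, the gut mesenchyme list lay at the threshold of the test and no other list passed it. The median log2 ratio of replicate 1 to replicate 2 over 201 shared peaks of 30 genes was −0.11 after centring, with 10 of the genes higher in replicate 1 (adjusted p = 0.044, permutation against matched random lists). The call rests on the random draw: 10 repeats of the draws, made after the result was seen, gave adjusted permutation p from 0.044 to 0.068, with 2 below 0.05. Gene medians ran from −0.86 at Twist1, with 1 shared peak, to 0.35 at Sfrp1, with 4. Foxf2 had a gene median of −0.58, Pdgfra of −0.39 and Tcf21 of −0.30, whereas Ptch1 had 0.10 and Meis1 0.13. All of these genes were picked after their values had been seen. The call ended in all 4 other settings tried (adjusted permutation p 0.15 to 0.56), with medians of −0.11 for distal peaks alone, −0.088 for an overlap of 1 base, −0.065 for −log10 q of at least 2 and −0.066 for at least 10. None of the other 16 lists with enough shared peaks passed; smooth muscle had a median of −0.065 (adjusted permutation p = 0.56), intestinal epithelium of −0.0016 (0.86) and endothelium of 0.10 (0.50).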

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

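The tests in this part were chosen after the lists had been seen. Peaks called on both pools together but left out of the replicated list, 55236 in number, are used above only as part of an alternative list, and they drew attention because they are not placed at random: 6.83% lay within 1 kb of a protein-coding TSS, against a mean of 1.88% and a highest value of 2.16% when they were shifted along the chromosomes (permutation p = 0.0099, one-sided, the smallest that 100 shifts can give). They were narrow and weak, with a median signal of 2.53 against 3.94 for replicated peaks, and 1167 genes had a promoter peak only among them. Their distal members were more numerous around intestinal epithelium (7.34 per gene against 2.33 in random lists, adjusted permutation p = 0.0015), smooth muscle (6.15 against 2.25, 0.0015), gut mesenchyme (7.06 against 3.30, 0.0028), stem cell and Wnt target (7.50 against 3.13, 0.0077) and housekeeping genes (3.75 against 1.24, 0.0023), and fewer around forebrain (0.826 against 2.90, 0.0099) and olfactory receptor genes (0.0379 against 0.953, 0.0015). The Hox (1.21 against 0.780, adjusted permutation p = 0.24) and erythroid lists (0.294 against 1.15, 0.11), which passed for the replicated peaks, did not pass.

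Scaffolds that are not placed on a chromosome held 6 replicated peaks, and no expected number was computed for them. The strongest, on an unlocalised scaffold of chromosome 4, was 1773 bp wide with a signal of 33.7; the others had signals of 2.7 to 4.74.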

How the results depend on the processing

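Added after the data had been seen were −log10 q of at least 10, matching on CpG ratio, peaks beyond 5 kb and noncoding start sites. The percent of replicate peaks shared, the promoter share of peaks, the numbers of lists with more or fewer distal peaks, of lists near large domains and of over-represented sequences, kept their side of the test or, for counts, stayed within 1.5 times in the settings run for each. Promoter share ran from 16.4% (both pools together) to 44.7% (−log10 q of at least 10), and from 18.3 to 21.2% with 1 pool left out. Genes with a promoter peak moved from 51.8% to 53.7% (2.5 kb window), 54.8% (every transcript start), 57.1% (both pools together) and 44.3% (−log10 q of at least 10), and were 53.0 to 55.2% with 1 pool left out. The number of peaks fell to 23332 and large domains to 454 at −log10 q of at least 10, since fewer peaks enter; 1 pool alone gave 78524 to 96031 peaks. The correlation of the pools was 0.824 at −log10 q of at least 2 and 0.781 at 10.

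With both pools together 8 lists were above the other genes at promoters and 7 below, in place of 5 and 12; Hox (76.9%), endothelium (87.5%) and enteric neural genes (80%) joined the first. Lists below numbered 7 to 11 with 1 pool left out and 4 after CpG matching, where CpG-poor promoters set the expected share. At −log10 q of at least 10 the endothelium list, which had no call in the main setting, was below the other genes, at 8.33%. The list that differed between pools was lost in all settings, with 0 lists for distal shared peaks alone, for −log10 q of at least 2 and of at least 10 and for an overlap of 1 base; with distal shared peaks alone the gut mesenchyme median, −0.11, was as low as before. The cause was not tested. Among values of single lists, genes and sequences, 862 were the same, which includes values without a call in both settings. A call was lost for 40 and gained on the same side for 15, while 17 values moved. A further 1, that of the endothelium list above, changed side and gained a call. Unknown depth limits all counts of weak peaks. No paired analysis was possible because there is 1 group.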

Other observations

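The tests of the signal on X, of the epithelium list between pools, of the Hox groups and of peaks beyond 5 kb were chosen after the values they concern had been seen, and the bound that would count against a lower dose of X was reworded afterwards to need a permutation test. Within the Hox clusters, the genes of paralogue groups 10 to 13 had a promoter peak in 4 of 12 cases (33.3%) and those of groups 1 to 9 in 22 of 27 (81.5%; p = 0.0079, two-sided Fisher's exact test). Neighbouring Hox genes can share peaks and are not independent, so this p is approximate, and the hypothesis that acetylation of these pools stops short of the posterior end of the clusters rests on the same genes that prompted it.

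Recognition sequences were also compared between gene lists, as hypotheses written down before the counts were made. Adjusted p-values here are over the pairs of sequence and list named in this paragraph. Distal peaks nearest smooth muscle genes contained the SRF CArG box in 12 of 106 cases (11.3%), against 4.09% in random lists of genes with as many distal peaks (adjusted p = 0.018, permutation), which is consistent with SRF sites near genes that SRF is known to drive. The CDX consensus was found in 21.9% of the peaks nearest intestinal epithelium genes against 17.3% (adjusted permutation p = 0.25) and the GATA consensus in 32.0% against 27.6% (0.27), both inside the random range. HNF4 was found in 2.02% of these peaks against 2.97% (adjusted permutation p = 0.46), the E-box in 37.9% of the peaks nearest gut mesenchyme genes against 42.2% (0.45) and ETS in 1.22% of the peaks nearest endothelial genes against 1.55% (0.93), so no rise near these lists was found. The bound set beforehand, a share at or below the median of random lists, was met for HNF4 (percentile 19.3) and the E-box (14.9), but it was judged too loose after the counts were seen, since the shares lie inside the central 95% of random lists (1.05 to 5.21% and 34.2 to 50.3%), and a rise stays open.

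The X chromosome had 3.87 replicated peaks per Mb and autosomes 20.7, and 30.3% of 948 X genes had a promoter peak against 53.2% of autosomal genes. X genes have fewer CpG-rich promoters (27% against 47.2% with a ratio of at least 0.6), but among genes with such promoters 65.2% on X and 84.3% on autosomes had a peak (p = 2.1e-13, two-sided Fisher's exact test), which argues against CpG content as the whole cause. The median promoter signal on X was 0.714 times that on autosomes (5.89 and 8.24, permutation p = 0.0002, the smallest 10000 permutations can give). For CpG-rich promoters the medians were 6.96 and 9.14. The signal is made against a control alignment, whose X reads would fall with dose too. The control was not analysed and the scale of the signal is not stated, so the ratio cannot test a lower dose of X in male embryos. Acetylated X genes had 0.568 distal peaks and autosomal ones 2.16, although the median sequence assigned to X genes was 1.69 times as long. That argues against shorter assigned sequence as the cause. How much of this sequence reads can be aligned to was not measured, so less usable sequence stays open. The median signal of the X distal peaks was 1.04 times the autosomal one (permutation p = 0.15), which says nothing about dose for the same reason. The dose, the kinds of gene on X and X inactivation in females stay open, and no biological explanation was tested, since the pools were not separated by sex.

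Housekeeping genes had as many distal peaks as some tissue lists. If flanks of their promoters had been counted as distal, leaving out peaks within 5 kb of a TSS should have removed the excess, but housekeeping genes then still had 3.77 times the distal peaks of random lists (adjusted permutation p = 0.016) and intestinal epithelium genes 4.42 times (adjusted p = 0.0023). The share of distal peaks within 5 kb was 17.2% for housekeeping genes, 23.9% for epithelium genes and 16.9% for all assigned peaks. Assignment to the nearest TSS does not show which gene a peak acts on, so enhancers of neighbouring genes stay open, and no biological explanation was tested. All 20 housekeeping genes had a promoter peak and the random lists were not matched on that, so its part in the excess is unknown.

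The lower signal of gut mesenchyme genes in replicate 1, which passed its test in 2 of 10 repeats of the random draws, was weighed against technical trends. Correcting the ratio for 20 bins of mean signal and of GC content moved the list median from −0.11 to −0.085, and its percentile among random lists from 0.14 to 0.55. That meets the bound set beforehand, below the 2.5th percentile, which was judged too loose only after the result was seen because it ignores the number of lists; over the same 17 lists and draws the adjusted p went from 0.051 to 0.19 as the median moved toward 0, so a trend as part of the pattern stays open. With 1 gene left out at a time, the highest median was −0.0816, without Col1a1 and its 20 peaks. That is still below the −0.068 that bounds the lowest 2.5% of random lists, so no single gene made up the whole shift. This bound also ignores the number of lists, and no adjusted p was computed without Col1a1. Whether its peaks carry the call therefore stays open. A smaller share of mesenchyme in the first pool would raise other cell types, and the epithelium list lay at the 39.2 percentile of random lists, within their range, so this stays open too; the design holds no group that could serve as a biological explanation.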
